A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

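Chromatin immunoprecipitation sequencing (ChIP-seq) was carried out on meiotic cultures of the budding yeast *Saccharomyces cerevisiae*. Either the transcription factor Bas1 or the transcription factor Ino4 carried a Myc epitope tag, and both were precipitated with the same anti-Myc antibody, per the labels. Each tagged protein had 1 ChIP library and 1 input library, taken 4 h into meiosis, so the 4 groups held 1 library each. The labels state no replicates, and no p-value was computed.

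The deposited files hold signal, as a whole-number coverage (read depth) for every base of 16 nuclear chromosomes and the mitochondrial genome, not normalized by the authors as far as the values show. Per the submitters' processing notes, the tool was BWA 0.7.5a-r405 and the genome build was sacCer2. Read numbers, fragment length and the handling of duplicates and of reads with several matches are not given in the sources used here. The library pairs differ in their uncovered bases. The Bas1 ChIP and input had 532619 and 533481 nuclear bases at a depth of 0, against 78513 and 81315 in the Ino4 ChIP and input. Of 509567 bases at 0 in both Bas1 libraries, 355336 (69.7%) were covered in both Ino4 libraries. Ratios were therefore formed within a pair of libraries, and comparisons across pairs carry this difference, whose source was not tested.

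Depth was divided by the nuclear median of its library. Enriched regions were stretches where the 200 bp running mean of the ChIP was at least 2 times that of its own input, with input at least 0.25 of the median, a width of at least 100 bp and gaps of up to 200 bp merged. The same rule was applied with ChIP and input exchanged and with 1 input over the other. Overlap of the region sets was set beside 1000 circular shifts. Promoters were the 500 bp upstream of start codons, measured as mean ChIP over mean input. In place of a replicate error, the SD over promoters of log2 Bas1 input over Ino4 input was used, which was 0.31. It holds differences of strain, library and any upstream processing together. For 14 gene lists the median log2 was placed among 10000 random lists of the same size, which describes these libraries only. The random lists were matched on depth deciles of the factor's own input, also where another denominator was used. Shares have exact (Clopper-Pearson) 95% intervals that cover counting error only.

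Gene names came from a table of assembly R64, a different build from that of the files. None of its coordinates are printed and none were converted. Its positions were used as they stand only where the depth itself showed them to be close: mean depth profiles at gene starts and ends on the other chromosomes were slid along windows of about 60000 bp. In 191 of 201 windows, 95.0% of the genome, the offset was at most 52 bp, with a median of 8 bp. The other 10 windows were left out. They were 8 windows of chromosome XI from position 181759 on, where the offset was 332 to 368 bp, and the last windows of chromosomes I and XIV. Of 6002 coding genes, 282 lay there and were not placed, BAS1 among them. Promoter values are approximate by these offsets. This use of positions across builds was chosen after the files were seen. Coordinates printed here are those of the files (sacCer2).

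The gene lists, region rules, promoter length and alternatives, except those named below as added later, were fixed before the data were examined. So was the rule for named genes: per factor the 12 highest promoters, with divergent promoters counted once; the 2 highest members and the lowest of each list made for a factor; HIS4, BAS1, INO4, INO2 and INO1; and the 5 highest regions per factor and shared. Other genes named were chosen after their values were seen, as stated where they appear. Chosen after seeing the data were also the classes of regions: those at gaps between the innermost genes of the chromosome arms (centromere gaps), those with input under 0.5 of the median at the summit or next to unmapped bases (runs at depth 0 in the Bas1 input, used for both factors), and those within 500 bp of a tRNA gene. So was the place at which centromere gaps were read, the lowest 200 bp mean of the Bas1 input in the gap or within 100 bp of it. The middle of the gap and other gaps between genes, of 300 bp to 3 kb, were added later. A region was assigned to a gene when its summit lay up to 1000 bp upstream or 100 bp inside its start. All 235 list genes matched the table, and 230 were placed.

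The steps were tested on simulated depth. Peaks implanted at 3 fold and 5 fold were recovered in 100% of 48 and 46 sites at the Bas1 depths and of 44 and 50 sites at the Ino4 depths, with 0 false regions. At 2 fold, the threshold itself, 27.3% of 44 and 25.9% of 54 sites were recovered. These simulations hold counting noise only, not differences between real libraries. Of 49 promoters raised 2 fold, the median measured log2 was 0.93 at the Bas1 depths and 0.94 at the Ino4 depths. After chromosomes II, VII and XV were moved by 40, -200 and 350 bp, the change in offset was found within 12 bp in all of 14, 18 and 18 windows. The same depth was moved, so this does not test whether the offsets before the move were right. Alternatives changed the threshold, the running mean, the scaling, the denominator, the input floor and the promoter length. Motif counts at summits had been planned and were not run, since no genome sequence was used here. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.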

Results

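Bas1 and Ino4 binding was measured across the genome of meiotic yeast, with 1 ChIP and 1 input library for each tagged protein. Bas1 is a Myb-family activator of purine, histidine and glycine metabolism genes, and Ino4 is a basic helix-loop-helix protein that acts with Ino2 on phospholipid genes. The median nuclear depth was 108 in the Bas1 ChIP, 283 in the Bas1 input, 400 in the Ino4 ChIP and 283 in the Ino4 input. There were no replicates, so every difference compares libraries and has no replicate check. The SD of log2 input over input across promoters, 0.31, is given as the available measure of library difference.

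The tag was looked for first, as a check of the labels, because a sequence inserted at the end of a gene interrupts alignment there. At the end of INO4, the lowest depth over that of the flanks was 0.0124 in the Ino4 ChIP and 0 in the Ino4 input, both at position 111431 of chromosome XV. It was 0.910 and 0.847 in the Bas1 ChIP and input. BAS1 lies in the part of chromosome XI where gene positions were not placed. With an offset of 332 bp in that window, the planned search of 100 bp did not reach the end of the gene. It gave 1.00 and 1.21 in the Bas1 ChIP and input. A search of 500 bp, chosen after seeing the data, found a depth of 0 at position 637922 in the Bas1 ChIP and 637923 in the Bas1 input, against ratios of 0.792 and 0.783 in the Ino4 ChIP and input.

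Which sites Bas1 occupied was asked by setting its ChIP against its input. The highest enrichment lay upstream of genes of the glycine cleavage system, which feeds the folate pathway. The region with its summit between GCV2 and MRPS17 reached 47.3 fold (chromosome XIII, 633839 to 641492). It was 7654 bp wide and also covered coding sequence. The region with its summit upstream of GCV3 reached 28.3 fold (chromosome I, 57172 to 59700) and that upstream of GCV1 24.7 fold (chromosome IV, 483837 to 487172). A region with its summit between MET6, the methionine synthase gene, and IES5 reached 24.1 fold (chromosome V, 341917 to 343130). A region of chromosome XI from 589043 to 591753 reached 28.1 fold. It was not assigned to a gene, since gene positions were not placed there.

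In all, 99 Bas1 regions passed 2 fold. The exchanged rule, input over ChIP, gave 270, and Bas1 input over Ino4 input gave 70, so at 2 fold the ChIP gave fewer regions than the exchanged rule. Of the 99 regions, 15 lay at placed centromere gaps and 38 in stretches of low input or beside unmapped bases, where the median scaled ChIP depth was 0.788 and the input 0.253. The remaining 46 had a median ChIP depth of 4.10. Of their 43 placed summits, 29 lay up to 1000 bp upstream of a gene start or 100 bp inside it. The share of the genome that meets this rule was not computed. Of the placed Bas1 summits, 93.4% (95% interval 86.2 to 97.54%, n = 91) lay outside coding sequence, against 26.9% of the placed genome. Without the centromere and low-input regions it was 88.4% (38 of 43, 74.9 to 96.1%). The 46 also held weak regions of chromosome I, such as those with summits at 51757, 65628 and 34470 (2.41, 2.69 and 2.33 fold). How the regions spread over the chromosomes was not computed.

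Ino4 sites were asked for in the same way. The highest regions lay upstream of fatty acid synthase and inositol genes. FAS1 reached 60.3 fold (chromosome XI, 98997 to 100611), with a summit farther upstream than the 500 bp promoter window, which held 3.31 fold. ITR1, an inositol transporter gene, reached 38.4 fold (chromosome IV, 1443892 to 1447092) and FAS2 34.5 fold (chromosome XVI, 106908 to 109781). The region with its summit between CPT1 and NRK1 reached 26.9 fold (chromosome XIV, 379369 to 382313), and INO1, which encodes inositol phosphate synthase, 22.0 fold (chromosome X, 135213 to 136882).

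Of 284 Ino4 regions, 13 lay at placed centromere gaps, 8 in low input or beside bases unmapped in the Bas1 input (3 and 5) and 263 elsewhere. At the summits of those 5 the Ino4 input was 0.555 to 0.864 of its median, so they were covered in the Ino4 libraries. Of the 256 placed summits among the 263, 211 lay up to 1000 bp upstream of a gene start or 100 bp inside it, a rule whose share of the genome was not computed. The exchanged rule gave 2 regions, and Ino4 input over Bas1 input gave 234. The share of Ino4 summits outside coding sequence was 75.4% (95% interval 69.8 to 80.3%, n = 276), against the same 26.9% of the placed genome. With the mean of both inputs as denominator the count was 554.

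**Figure D1:**
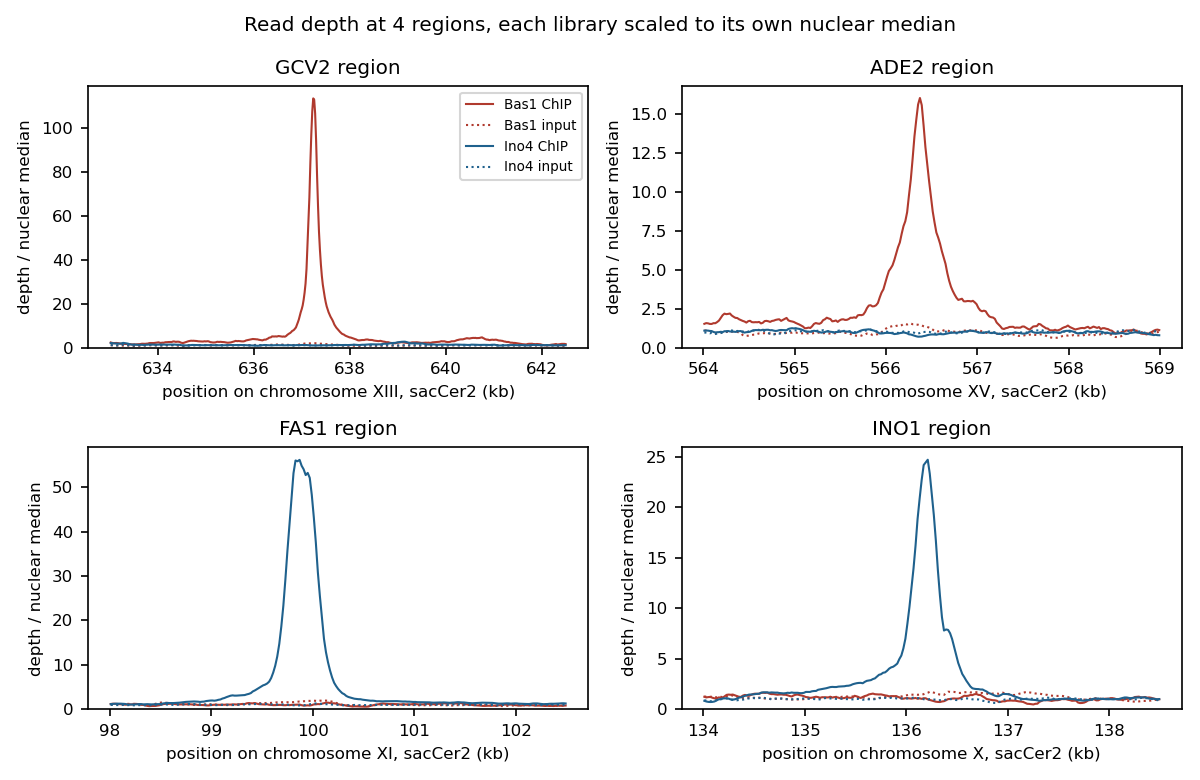
Read depth over the nuclear median (vertical axis) by position in kb (horizontal axis) around GCV2, ADE2, FAS1 and INO1, with ChIP as solid and input as dotted lines, Bas1 in red and Ino4 in blue. The Bas1 ChIP rises at GCV2 and ADE2 and the Ino4 ChIP at FAS1 and INO1, while the inputs change little on this scale; the 200 bp mean fold was 47.3 at GCV2 and 60.3 at FAS1.

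Over promoters, 40 of 5547 had Bas1 ChIP over input of at least 2, and 129 of 5659 had Ino4 ChIP over input of at least 2. The 40 included BOL1 and KIN3 of chromosome I (Bas1 log2 1.11 and 1.02), named after their values were seen. How the 40 spread over the chromosomes was not computed. At most 0.5 fold was found at 28 promoters for Bas1 and 0 for Ino4; over the Ino4 input it was 171 for Bas1, and over the Bas1 input 82 for Ino4. Among placed genes, the highest Bas1 promoters were GCV2 and MRPS17 (30.8 fold each), GCV3 (18.4), GCV1 (17.0), IES5 and MET6 (14.8 and 12.4), ADE2 (7.73), ADE4 (6.51), SHM2 (5.27), ADE17 (5.04), ADE1 and BUD14 (4.10 and 4.09), STR3 (3.67), ADE12 and POP1 (3.63 and 3.54) and HIS1 (3.44). SHM2 encodes a serine hydroxymethyltransferase and STR3 a cystathionine lyase. The highest Ino4 promoters were ITR1 (25.9), FAS2 (22.8), CPT1 and NRK1 (18.1 and 13.6), INO1 (14.4), CDS1 and RKM3 (13.3 and 12.4), EKI1 and SWI5 (11.7 and 4.40), CHO2 (10.6), OPI3 and MOG1 (10.1 and 6.60), KEL2 (8.95), YBR085C-A (8.69), YMR084W (8.43), and RSF1 and FAR8 (7.42 and 7.20). CHO2 and OPI3 encode the phosphatidylethanolamine methyltransferases. The median promoter log2 was -0.26 for Bas1 and -0.09 for Ino4; with the Ino4 input as denominator it was 0.02 for Bas1.

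**Figure D2:**
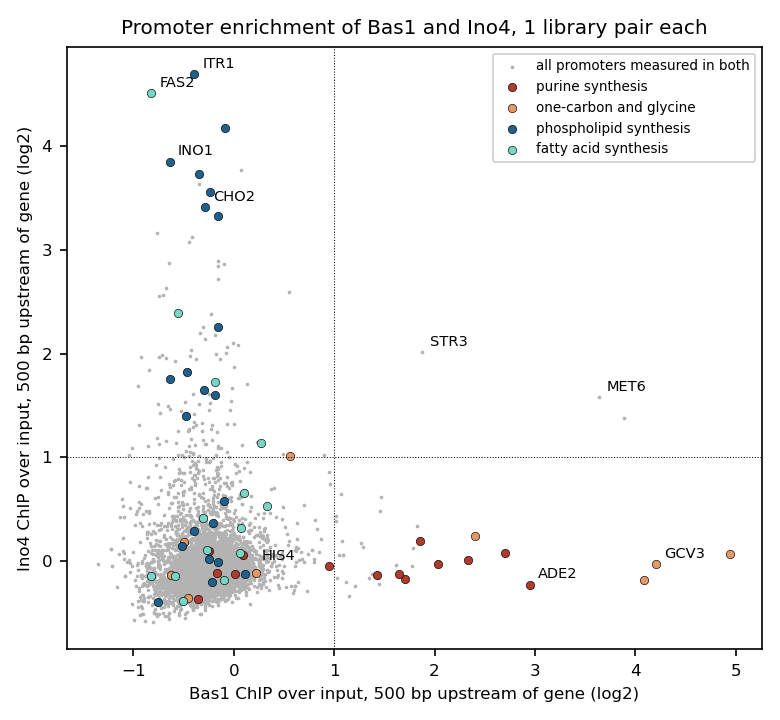
Each dot is a promoter, with Bas1 ChIP over input (log2) on the horizontal and Ino4 ChIP over input (log2) on the vertical axis; colours mark 4 gene lists and dotted lines 2 fold. Purine, glycine and folate promoters extend along the horizontal axis and phospholipid promoters along the vertical axis, and 3 promoters pass 2 fold in both. These are IES5 and MET6, which are divergent and counted once elsewhere, and STR3.

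Among the lists chosen for Bas1, purine synthesis stood highest, with 8 of 14 promoters at 2 fold or more and a median log2 of 1.54, above all 10000 random lists. ADE2 (2.95) and ADE4 (2.70) were highest and GUA1 (-0.36) lowest. The list of folate and glycine metabolism had 10 members, of which MTD1 was not placed and not measured. Of the other 9 promoters 4 passed 2 fold, with a median of 0.56, also above all random lists, GCV2 (4.95) and GCV3 (4.20) highest and MIS1 (-0.62) lowest. That median moved with the processing, to 0.83 over the mean of both inputs and 1.16 over the Ino4 input, and it was lower with 1000 bp upstream. Of 7 histidine genes 1 passed, and the median was 0.07, at the 99.8th percentile; HIS1 was at 1.78, HIS5 at 0.35 and HIS3 at -0.40. Amino acid genes known as Gcn4 targets had a median of -0.27, at the 94.0th percentile, with 1 of 26 at 2 fold or more; MET6 was at 3.63, ILV5 at 0.87 and ARG3 at -0.75. Phosphate genes had a median of -0.51, at the 29.6th percentile, with 0 of 8 at 2 fold; PHO89 was at 0.90, PHO5 at -0.12 and PHO81 at -0.72. In the Ino4 libraries the medians of these 5 lists were -0.08, -0.03, -0.05, -0.02 and 0.31.

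Among the lists chosen for Ino4, phospholipid synthesis had 13 of 22 promoters at 2 fold or more and a median of 1.63, above all random lists, ITR1 (4.69) and CPT1 (4.18) highest and ITR2 (-0.40) lowest. Fatty acid synthesis had 4 of 14 and a median of 0.37, above all random lists; FAS2 was at 4.51, FAA1 at 2.39 and PPT2 at -0.39. With the Bas1 input as denominator, chosen after seeing the data, the fatty acid median was -0.17, where that of all promoters was -0.37, and stood at percentile 96.3 among random lists. The regulators of inositol genes had 2 of 6 and a median of 0.44, at the 99.9th percentile, with INO2 at 1.13, INO4 at 1.06 and HAC1 at -0.42. In the Bas1 libraries the medians of these 3 lists were -0.27, -0.23 and -0.42. The other lists lay between percentiles 22.9 and 91.0 of the random lists for Bas1 over its own input: sterol synthesis -0.36, highly expressed, mostly glycolytic genes (the glycolytic list) -0.38, ribosomal proteins -0.39, respiration -0.44, early meiosis -0.22 and middle meiosis -0.25. For Ino4 they were -0.08, 0.20, -0.03, -0.06, -0.20 and -0.07, of which the glycolytic list was at the 99.98th percentile and early meiosis at the 0.35th percentile. The glycolytic list also held the translation elongation factor genes TEF1, TEF2, EFT1 and EFT2. These were among its 5 of 15 measured promoters below 0 for Ino4. With the mean of both inputs as denominator, the Ino4 medians of the glycolytic and phosphate lists were -0.09 and -0.01, where that of all promoters was -0.23. They stood at percentiles 97.7 and 99.2. Over the Bas1 input they were at 67.4 and 90.4, so both percentiles moved with the denominator. The random lists stayed matched on the Ino4 input, so a change of denominator is not separated from a loss of matching. Over the mean of both inputs early meiosis was at percentile 4.43, and ribosomal proteins, at 83.1 over the own input, were at 0.28.

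**Figure D3:**
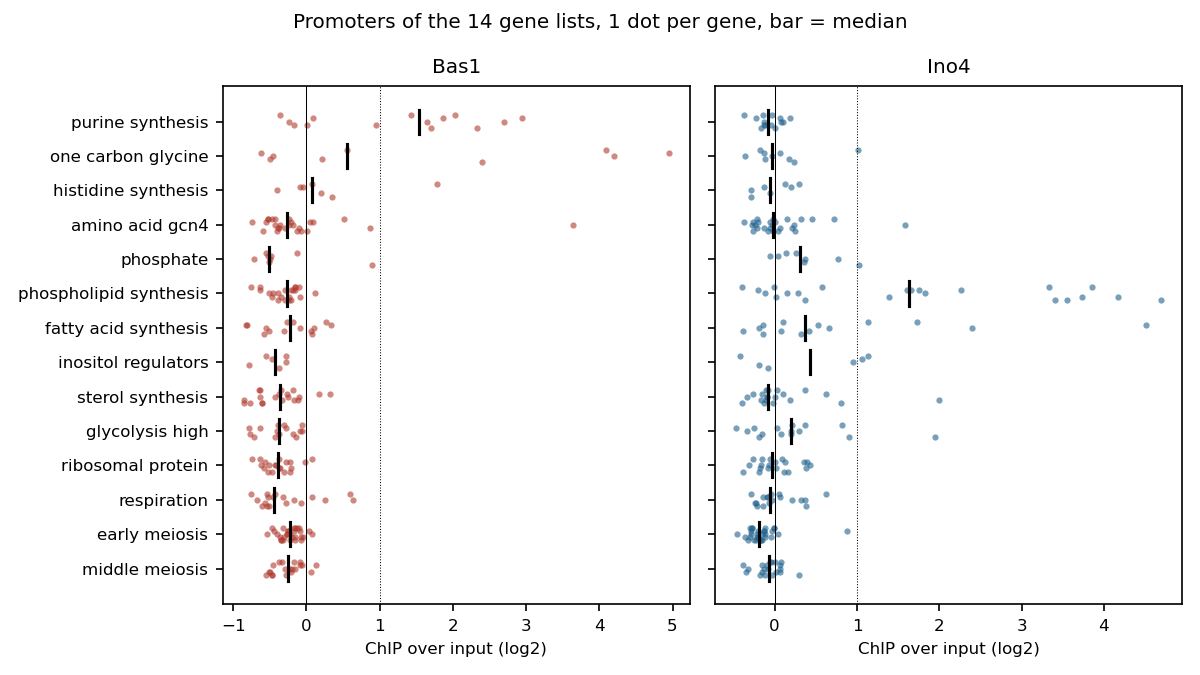
Promoter ChIP over input (log2, horizontal axis) for Bas1 (left) and Ino4 (right) in the 14 gene lists, 1 dot per gene with the median as a bar. The purine median is 1.54 for Bas1 and the phospholipid median 1.63 for Ino4.

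HIS4 is a known site of meiotic recombination whose activity has been tied to Bas1. Its promoter had 1.15 fold Bas1 ChIP over input (log2 0.20) and 0.964 fold for Ino4. The Bas1 value lay 0.46 above the median of all promoters, at their 95.8th percentile, against 0.04 and the 57.7th percentile for Ino4; the inputs differed by 0.14 at this promoter. The highest 200 bp mean upstream was 1.45 fold for Bas1, at position 68619 of chromosome III. For Ino4, its own promoter stood at 2.09 fold and that of its partner INO2 at 2.19; for Bas1 these were 0.720 and 0.827, and INO1 was 0.642. The BAS1 promoter was not measured since the gene was not placed.

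Both proteins carried the same tag, so overlapping regions were counted. Of the 99 Bas1 regions 20 overlapped an Ino4 region, against a mean of 2.35 and a highest of 8 over 1000 circular shifts. The shifts did not keep regions outside coding sequence, where most summits of both factors lay. They therefore cannot show overlap beyond that shared location. Of the 20, 11 lay at placed centromere gaps, and 2 of the other 9 had both folds at 3 or more at the Bas1 summit. The centromere gap of chromosome XI was not placed. Among the 9 was a region in the unplaced part of that chromosome (439677 to 439948), which could not be classed by gene positions. Its Bas1 and Ino4 folds were 3.56 and 2.22, with inputs of 0.537 and 0.734. Where the Bas1 input was lowest in the placed gaps, the medians were 3.99, 2.23, 0.523 and 0.695. This region also counts among the 46 Bas1 and 263 Ino4 regions elsewhere. Overlap does not mean a common summit: Ino4 was 1.04 fold at the GCV2 summit. The others included a region whose nearest gene start downstream was JEN1, a lactate transporter gene, too far to be assigned to it (chromosome XI, 20281 to 22104, 21.2 fold Bas1 and 5.25 fold Ino4), and another upstream of STR3 (chromosome VII, 156044 to 156600, 4.16 and 5.67 fold). Among the 5 with the highest lower fold were also 2 centromere gaps, on chromosomes VIII (105510 to 105767, 3.84 and 2.69 fold) and VII (496837 to 497142, 5.19 and 2.48 fold), and a region of chromosome XIII (632349 to 633583, 2.48 and 3.73 fold). The Bas1 summit of this last region lay in coding sequence, and the GCV2 region starts close by, at 633839. Whether the 2 are separate Bas1 sites was not tested. At 3 fold the shared count was 3.

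Where the Bas1 input was lowest in each of the 15 placed centromere gaps, Bas1 ChIP over input had a median of 3.99 and Ino4 ChIP over input of 2.23. The scaled depths had medians of 1.90 in the Bas1 ChIP and 0.523 in its input, and 1.45 in the Ino4 ChIP and 0.695 in its input. This place was picked on the denominator. At the middle of the gaps the medians were 1.92 and 1.73, with Bas1 ChIP at 2.09 and Bas1 input at 1.19. In 3152 other gaps between genes, read where the Bas1 input was lowest, the median Bas1 ChIP over input was 1.02. The median Bas1 input there was 0.990, so these gaps do not show what a place of low input gives. Upstream of start codons the Bas1 input was above its own nuclear median, at 1.28 at 200 bp upstream, against 1.01 in the Ino4 input, 0.963 in the Bas1 ChIP and 0.913 in the Ino4 ChIP.

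**Figure D4:**
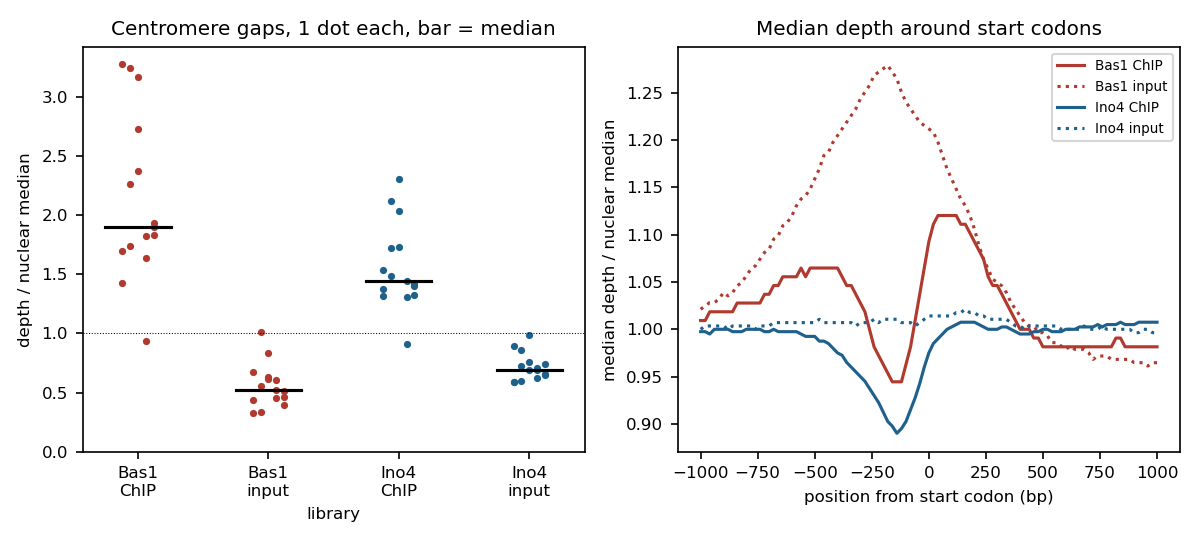
Left, depth over the nuclear median where the Bas1 input is lowest in each of the 15 placed centromere gaps, by library, with the median as a bar; right, median depth over the nuclear median by distance from the start codon in bp. The ChIP libraries lie above and the inputs below 1 at most gaps, with medians of 1.90 and 0.523 for Bas1, and the Bas1 input is raised upstream of genes.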

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

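The tests in this part were chosen after the results were seen. Several lists had medians of opposite sign in the Bas1 and Ino4 libraries. With 1 library each, these differences were not tested. Over the own inputs, Bas1 minus Ino4 median log2 was 1.62 for purine synthesis, 0.59 for folate and glycine metabolism, 0.12 for histidine synthesis, -0.81 for phosphate genes, -1.89 for phospholipid synthesis, -0.60 for fatty acid synthesis, -0.86 for the inositol regulators and -0.58 for the glycolytic list. Over the mean of both inputs, the Bas1 and Ino4 medians were -0.12 and -0.09 for the glycolytic list and -0.10 and 0.01 for fatty acid synthesis. They were -0.24 and -0.01 for phosphate genes, 1.68 and -0.22 for purine synthesis and -0.15 and 1.47 for phospholipid synthesis. The glycolytic, fatty acid and phosphate differences thus depended on the denominator. For the HIS4 promoter, Bas1 minus Ino4 over the own inputs was 0.25. The median of all promoters was itself -0.26 for Bas1 and -0.09 for Ino4, and relative to these the HIS4 difference was 0.43. The SD of the same difference over all promoters was 0.49, and HIS4 stood at percentile 95.1 of them. The difference was 0.30 (percentile 88.6) over the mean of both inputs and 0.13 (percentile 64.2) over the other input.

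All 15 placed centromere gaps held a Bas1 region, with the lowest at 3.14 fold. The depths in the report were read where the Bas1 input was lowest in each gap, a place picked on the denominator, and at the middle of the gaps the median Bas1 ChIP over input was 1.92 instead of 3.99. Low input depth alone is argued against as the whole cause, since the median scaled ChIP depth was 1.90 at the first place and 2.09 at the middle, where the input was not low (1.19). Ino4 ChIP over input was at least 1.5 at 14 of the 15 gaps where the Bas1 input was lowest but at 9 at the middle, so precipitation that does not depend on which tagged protein is present stays open. No untagged strain was analysed here, and a biological explanation was not tested.

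Bas1 ChIP lay below input at promoters in general. With the Ino4 input as denominator the median log2 was 0.020. This follows nearly by arithmetic from the median difference between the inputs, 0.30, so it does not test whether an excess of promoter DNA in the Bas1 input is the cause, which stays open. Both ChIP libraries also lay below their own nuclear median at 200 bp upstream of start codons, at 0.963 for Bas1 and 0.913 for Ino4. The library pairs also differed in their uncovered bases, for which no source was tested.

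Whether the Bas1 regions in low input hold missing input fragments or extra ChIP fragments stays open. In 89.5% of the 38 such regions (34) the scaled ChIP depth at the summit was at most 1.2, but these regions were picked for their low input, so the value restates the choice. Of them 18 lay within 500 bp of a tRNA gene, a class with repeated sequence, while over 261 tRNA genes the median Bas1 ChIP over input was 0.864. No biological explanation was tested.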

How the results depend on the processing

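No paired analysis was possible because each group held 1 library. Motif counts at Bas1 and Ino4 summits were not run under any setting. Changes in list medians were judged against the 0.31 SD of single promoters, a lenient bound for a median. The other factor's input as denominator, the input floor of 0.5, gene positions moved by 50 bp, the 500 bp tag search and the subset away from centromeres and low input were added after seeing the data. The cause of a change was not tested. By construction, a maximum lies above a mean, and the mean of both inputs raises the Ino4 fold where only the Bas1 input is at 0. Of the 378 values recomputed for the comparisons, 299 stayed within their bound, 73 moved beyond it and 6 medians at the extremes of the random lists changed sign. Counting any list or HIS4 value, 44 of 298 changed sign, 25 for Bas1 and 19 for Ino4. Of 297 values of single named promoters, 119 moved beyond that bound and 178 did not. Among the comparisons, moving gene positions moved none beyond it.

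At thresholds of 1.5, 3 and 5, Bas1 regions numbered 572, 45 and 13, Ino4 regions 531, 121 and 52, and shared regions 47, 3 and 1. At 1.5 and 3, Bas1 promoters numbered 73 and 20, and Ino4 promoters 268 and 61. Summits outside coding sequence at 3 fold were 97.6% for Bas1 and 84.9% for Ino4. A running mean of 500 bp gave 8 shared regions. A pseudocount of 0.05 without a floor gave 167 Bas1 regions. Ino4 regions numbered 554 over the mean of both inputs, 481 over the Bas1 input and 526 over the Bas1 ChIP.

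List medians are log2, and a denominator also moves all promoters: their median was -0.09 for Ino4 over its own input, -0.23 over the mean of both and -0.37 over the Bas1 input, and -0.26, -0.14 and 0.02 for Bas1 over its own, both and the Ino4 input. A sign change is thus not by itself a loss. Percentiles among random lists moved too, with the random lists still matched on the factor's own input. For Ino4, over the mean of both inputs and over the Bas1 input, ribosomal proteins were at 0.28 and 0.01, early meiosis at 4.43 and 9.80 and middle meiosis at 12.8 and 1.27. For Bas1, over the mean of both inputs and over the Ino4 input, middle meiosis was at 98.9 and 98.6 and ribosomal proteins at 60.3 and 98.7. Over the mean of both inputs the Ino4 medians of the glycolytic list and of phosphate genes changed sign, to -0.094 and -0.0080. Fatty acid synthesis was there at 0.0089 and ribosomal proteins at -0.37. Over the Bas1 input, Ino4 medians changed sign for fatty acid synthesis (-0.17), the glycolytic list (-0.34) and phosphate (-0.24), at percentiles 96.3, 67.4 and 90.4 of random lists under that denominator. There histidine was -0.39, Gcn4 targets -0.43, sterol -0.51, folate and glycine -0.51, respiration -0.51, middle meiosis -0.54, ribosomal proteins -0.63 and phospholipid 1.28. Over the Ino4 input, Bas1 medians were Gcn4 targets 0.092, glycolytic 0.13, middle meiosis 0.17, folate and glycine 1.16, phosphate 0.049, respiration 0.088, ribosomal proteins 0.19 and sterol -0.0020. Over the other ChIP, Bas1 medians were Gcn4 targets 0.11, early meiosis 0.24, glycolytic 0.022, middle meiosis 0.27, phosphate -0.11, phospholipid -1.67, purine 1.93, respiration 0.19, ribosomal proteins 0.23 and sterol -0.029. Ino4 medians there were glycolytic -0.022, which changed sign, fatty acid 0.039, folate and glycine -0.73 and purine -1.93, and HIS4 was -0.39.

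With 1000 bp upstream, Bas1 purine was 1.14, Bas1 folate and glycine 0.20 and Ino4 phospholipid 1.197. With the highest 200 bp mean, Bas1 promoters numbered 76 and Ino4 promoters 267, and HIS4 stood at 0.54 for Bas1. Bas1 medians were then Gcn4 targets 0.10, fatty acid 0.13, glycolytic 0.018, middle meiosis 0.075, folate and glycine 0.87, phosphate 0.11, purine 1.90, respiration 0.079, ribosomal proteins 0.080 and sterol 0.0080, and Ino4 phospholipid was 1.99. The BAS1 tag ratio in the Bas1 ChIP and input was 0.266 and 0.445 within 300 bp and 0 in both within 500 bp. Across all settings the purine median for Bas1 (1.14 to 1.93) and the phospholipid median for Ino4 (1.197 to 1.99) stayed above 1. Of the highest promoters, only STR3 for Bas1 had a log2 below 1, at 0.10 over the Ino4 ChIP, which is itself enriched there (4.03 fold).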

Other observations

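Several genes of methionine metabolism, all but MET6 outside the lists, had high values in the Ino4 libraries. Promoter ChIP over input was 7.29 fold at SAH1 (adenosylhomocysteine hydrolase), 6.18 at ADO1 (adenosine kinase), 5.87 at MET13 (methylenetetrahydrofolate reductase), 4.03 at STR3, 3.93 at SAM2 (adenosylmethionine synthetase) and 2.99 at MET6. These genes were chosen for their high values, so they test nothing about the pathway. Others of it were not enriched: SAM1, which encodes the same activity as SAM2, stood at 0.882 fold, MET12, a relative of MET13, at 0.817, MET7 at 0.926, MHT1 at 0.983 and SAM4 at 0.995. MET6 and STR3 were also enriched for Bas1, at 12.4 and 3.67 fold.

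It was then asked whether Ino4 enrichment may extend to other sulfur amino acid genes, a hypothesis of this re-analysis. The list and the bounds were written before the test was run, but after the values of all promoters had been tabulated, and the list left out genes already seen to be high, which pulls its median down. MET14 had been seen earlier, is not placed and was not measured. In 16 measured genes of 17 the median log2 was -0.02, at the 91.0th percentile of 10000 random lists, between the bounds set in advance, and 0 promoters passed 2 fold. The highest were MET17 at 1.77 fold and MET8 at 1.40, and a 162 bp Ino4 region of 2.27 fold was assigned to MET17. The test leaves the question open.

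Median scaled depth over LYS2 was 1.88, 1.83, 2.03 and 2.00, and over LEU2 2.43, 2.29, 2.30 and 2.04, in the Bas1 ChIP, Bas1 input, Ino4 ChIP and Ino4 input. HO held 89 bases near a depth of 0 in both Bas1 libraries and 88 in both Ino4 libraries. Mitochondrial mean depth over the nuclear median was 2.95, 4.46, 2.06 and 18.0 in the same order.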
